A study of Homo sapiens with 32 samples.

How the data were processed

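Transcript levels were measured on 32 Affymetrix arrays of a small custom design that holds mainly glycosylation-related genes, 1259 probe sets in all. Each array was hybridised with biotin-labelled cRNA from total RNA of the AB 8/13 line, a human podocyte cell line (podocytes are the epithelial cells that cover the filtering capillaries of the kidney). Per the submitters' processing notes, the probe signals were summarised with RMA, a method that corrects the background, normalizes between arrays and gives 1 value per probe set. No version of RMA and no number of normalization runs are given in the sources used here. The values deposited by the authors are on the log2 scale and lay between 2.42 and 14.35, with array medians between 6.13 and 6.33. Scanner files and detection calls were not used here, so no signal was compared with a measured background.

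Per the labels, the arrays form 10 groups, namely normal culture with 5 arrays and 9 treated groups of 3. The labels do not say that replicates came from separate cultures, so the p-values measure only the spread between these samples, which may be technical. The source descriptions come in 2 styles of wording, which divided the arrays into label set 1 with 12 arrays and label set 2 with 20 arrays. Set 1 holds normal culture replicates 1 to 3, the starved cells, the cells given 200 nM insulin and the cells in 25 mM glucose. Set 2 holds normal culture replicates 4 and 5, the cells given 50, 75 and 100 nM insulin, the glucose-free cells and the cells in 5 and 15 mM glucose. Whether the sets were processed apart is not given in the sources used here. For the 15 mM group the title and source description give 15 mM and another label field gives the same figure in nM; the title was followed.

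Probe sets carry RefSeq accessions, which were matched without their versions to the gene table of assembly GRCh38.p14, used only for names. Of the 1259 probe sets, 1043 matched 1 gene symbol, 26 carried an accession that the table does not hold and 190 carried no RefSeq accession. The 216 unnamed probe sets stayed in every test. The named ones cover 927 genes, 93 of them with more than 1 probe set. The table names 0 control probe sets, and it does not show the species of a probe set, so no fit without probe sets of another species could be made.

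All 32 arrays entered 1 linear model in limma 3.58.1 under R 4.3.3, with a mean for each of 11 cells, the 9 treated groups and normal culture divided by label set. The fit left 21 residual degrees of freedom, to which the empirical Bayes step added 4.35. Each of 14 comparisons was a two-sided moderated test with Benjamini-Hochberg adjustment over the 1259 probe sets, and a probe set was called at an adjusted p under 0.05. The insulin groups of 50, 75 and 100 nM lie in another label set than the starved cells, and 25 mM glucose in another than the glucose-free cells. Those 4 comparisons were bridged through normal culture: the difference of each group from the normal culture of its own set was taken first, and then the difference between these differences, which takes the difference between the normal cultures as shared by all arrays of set 2. Glucose-free medium and the pooled insulin groups were compared with normal culture replicates 4 and 5 only. The median 95% half-width of a log2 change, before any adjustment, was 0.18 within a label set with 3 arrays against 3, 0.20 with glucose-free medium against normal culture replicates 4 and 5, and 0.27 for a bridged comparison. The number of arrays limits this precision. For each probe set the fit used 1 spread for all cells. Normal culture replicates 4 and 5 differed by an SD of 0.445 over probe sets, against at most 0.303 for any other pair of replicates. The SEs, intervals and p-values of comparisons that use these arrays thus tend to be too small.

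Genes were named by a rule. For each comparison it takes the 12 called genes with the largest rise and the 12 with the largest fall among those whose arrays do not overlap between the groups (called only, for bridged comparisons), with the probe set of smallest p for each gene. It adds up to 4 called members of each gene list and, where fewer than 5 probe sets were called, the 5 with the smallest unadjusted p. List members were named and counted only for comparisons within a label set that leave out normal culture replicates 4 and 5. A panel was given whatever its result; 8 of its 14 genes are on the array, namely PODXL, IGF1R, GFPT1, GFPT2, OGT, OGA, GNE and CMAS. There were 33 gene lists on glycan synthesis, transport, breakdown and binding, on proteoglycans, on growth factors, cytokines and signalling, and on markers of podocytes and of other cells. The 26 lists with at least 5 measured genes were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry, adjusted over the lists of a comparison. Camera compares a list with the other genes of the array, which are largely glycosylation genes too. Fry tests whether the genes of a list move, on balance, in a shared direction, and its mixed form whether they change in either direction. The design, the lists, the naming rule and all alternatives but 1 were fixed before the data were examined. The limit on which comparisons name list members was not part of the rule as fixed.

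The alternatives were a fit without the label set, the label set as a random block, the replicate number as a block, a fit of only the arrays compared, quantile normalization between arrays, leaving out dim probe sets (highest group mean under the 25th percentile of all values, 4.59), empirical Bayes with trend and robust options, gene-level means, array weights, a 1.5-fold minimum, 1 probe set per gene in the list tests, and leaving out each array in turn. Leaving out normal culture replicates 4 and 5 together was added after seeing the data. Without replicate 4 or 5 alone, normal culture of set 2 is 1 array, and its spread is taken from the other cells. A call kept in such a fit does not show that a change was replicated.

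Whether shared replicate numbers pair the arrays was checked through the correlation, over probe sets, of same-numbered arrays' deviations from their group means. For 200 nM insulin against starved cells these correlations were 0.289, 0.132 and 0.123, all above 0.1, so those numbers were taken to pair the arrays; probe sets are not independent replicates. The blocked fit of that comparison called 0 probe sets, as did limma without the block, which found 42 at an unadjusted p under 0.05. In the other comparisons within a label set at least 1 of the correlations was below 0.1, with single values from -0.257 to 0.303. The correlations were not tested against chance.

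The fit was tested on simulated data with 50 probe sets changed at each of 4 fold sizes among 1259. For starved against normal culture it recovered 52% of the changes of 1.2-fold and 98% of those of 1.5-fold, and 5.91% of its calls were wrong. For 200 nM insulin against starved cells it recovered 50% at 1.2-fold and 98% at 1.5-fold. For 15 mM glucose against glucose-free medium it recovered 54% at 1.2-fold and 96% at 1.5-fold. For the bridged comparison of 100 nM insulin with starved cells it recovered 28% at 1.2-fold and 86% at 1.5-fold. The simulated arrays had no difference between label sets and no deviating arrays. The recovery of the bridged comparison therefore holds only where the assumption of the bridge is met. The figures were drawn with matplotlib 3.10.9 under Python 3.11.15.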

Results

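Transcript levels of AB 8/13 human podocytes were measured on 32 arrays in 10 groups, to find glycosylation-related genes that insulin and glucose modulate, a question raised by diabetic kidney disease. Normal culture, a serum-containing medium with an insulin supplement, had 5 arrays, and each of the 9 treated groups had 3. Starved cells were kept for 20 hours without serum and insulin. Cells given 50, 75, 100 or 200 nM insulin received it for 15 minutes after that starvation. Glucose groups were kept for 24 hours in glucose-free medium or in 5, 15 or 25 mM glucose. The sample titles give no glucose level for normal culture, and no serum or insulin for the glucose groups. Changes are log2 differences with their standard error (SE), and group levels are means with their SD. Of the genes named below, SPOCK3, IFNG, IL2RB, SULT1C2, GALK2, ST3GAL6, ST8SIA2, CLC, LY75, CD69, HGF, DCN and KLRB1 had dim signals, with every group mean of the probe set used under 4.59, the 25th percentile of all values. CHST9 lay above 4.59 only in starved cells and with 200 nM insulin. Signal over background was not measured, so the number of arrays is the stated limit on precision.

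Serum and insulin starvation was compared with normal culture replicates 1 to 3, which asks what withdrawal alone does before insulin is given. IL1B, which encodes the inflammatory cytokine interleukin-1 beta, rose 1.79-fold, from 7.94 ± 0.13 to 8.78 ± 0.19 (SD, n = 3 each). CHST9, an N-acetylgalactosamine 4-O-sulfotransferase, rose by 0.70 (SE 0.12), from 4.00 to 4.70, with a limma adjusted p = 0.00457. ST8SIA1, the synthase of ganglioside GD3, rose by 0.53 (SE 0.11), and SPOCK3, a testican proteoglycan, rose from 3.67 ± 0.05 to 4.12 ± 0.11. LFNG, the fringe enzyme that extends O-fucose on Notch receptors, changed by -0.38 (SE 0.08), and INHBA, a subunit of activin, by -0.41 (SE 0.10). IGFBP3, which binds insulin-like growth factors, changed by -0.27 (SE 0.06) at a high level of 12.17 ± 0.08. Other risers were TGFBRAP1 and CXCL14 with 0.60 each, LAMP3 with 0.56, SLC35F3 with 0.46, PF4 with 0.29 and RPL13A with 0.24, and IFNG changed by -0.30.

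By gene list, starvation moved single members. Of 20 measured sialyltransferase genes, 1 rose (ST8SIA1), and 2 rose when adjusted over the list alone. Of 18 chondroitin and dermatan sulfate genes, 1 rose (CHST9), with 1 higher and 1 lower adjusted over the list alone. Among 19 Notch pathway genes 1 fell (LFNG), and among 23 genes of TGF-beta and BMP signalling 1 fell (INHBA); adjusted over the list alone, both lists had 1 higher and 1 lower. Of 23 chemokine and cytokine genes 1 rose (IL1B), also when adjusted over the list alone. No list was called by camera, where the smallest adjusted p was 0.255. The mixed form of fry called the sialyltransferases and the FGF, VEGF, PDGF and EGF family, each with an adjusted p of 0.0431. Of the panel, 0 genes were called by limma; GFPT1, the entry enzyme of the hexosamine pathway, had -0.18, GFPT2 had 0.15, OGT had 0.14, IGF1R had 0.11, GNE had -0.09, CMAS had -0.05, OGA had -0.03 and podocalyxin (PODXL) had 0.00.

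limma called 18 probe sets between starved and normal culture, 13 higher and 5 lower, with 151 at an unadjusted p under 0.05; 3 of the called carry no gene symbol, and 5 changed at least 1.5-fold. The count was 6 without normal culture replicate 1, 6 without replicate 2 and 2 without replicate 3; it was 7, 9 and 11 without starved replicates 1, 2 and 3. Of the 14 named genes, 2 stayed called without any 1 array, CHST9 and SPOCK3. IL1B lost its call without normal culture replicate 1, 2 or 3 and without starved replicate 1 or 3, with adjusted p values up to 0.152. A fit of only these 6 arrays called 4 probe sets, and with probe sets averaged by gene LFNG was not called.

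Insulin at 200 nM for 15 minutes was compared with starved cells, which asks for its early effect on transcripts. The smallest unadjusted p values belonged to IL2RB, a subunit of the interleukin-2 receptor, with 0.20 (SE 0.06) and IFNG with 0.24 (SE 0.08). They were followed by ALG11, a mannosyltransferase of the N-glycan precursor, with -0.48 (SE 0.16), TGFBRAP1 with -0.45 (SE 0.16) and PF4 with -0.21 (SE 0.07). Each of these 5 had a limma adjusted p of 1.00. In the panel IGF1R, the receptor for insulin-like growth factor 1, had 0.23, GFPT1 had 0.18, OGA had 0.16, OGT had 0.12, PODXL had 0.09, GNE and CMAS had -0.02 each and GFPT2 had 0.00. limma called 0 probe sets, with 42 at an unadjusted p under 0.05, and no list was called by camera, with a smallest adjusted p of 0.676. The median 95% half-width of a change was 0.18 before any adjustment, and on simulated data the adjusted test of this comparison recovered 50% of changes of 1.2-fold and 98% of changes of 1.5-fold. Many probe sets were changed at once in those data, so the recovery of a few isolated changes would be lower.

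Glucose at 25 mM was compared with normal culture replicates 1 to 3, as the high-glucose arm of that label set. KLRC1, a lectin-like receptor of natural killer cells, rose 1.44-fold, by 0.52 (SE 0.09, n = 3 each) with a limma adjusted p = 0.00569. CXCL3, a neutrophil chemokine, rose by 0.46 (SE 0.10), GCNT2, the I-branching enzyme, by 0.46 (SE 0.11), SULT1C2, a sulfotransferase, by 0.38 (SE 0.09) and TNFRSF9, the receptor 4-1BB, by 0.37 (SE 0.09). POFUT1, the protein O-fucosyltransferase that modifies Notch, rose by 0.30 (SE 0.07) on 1 of its 3 probe sets, while another had the opposite sign. EPO, which encodes erythropoietin, changed by -0.46 (SE 0.09), the inhibin subunit gene INHBC by -0.40 (SE 0.07) and the adhesion molecule gene MADCAM1 by -0.36 (SE 0.07).

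Of 13 fucosyltransferase genes 1 rose at 25 mM glucose (POFUT1), and adjusted over the list alone 1 was higher and 1 lower. Of 19 Notch pathway genes 1 rose (POFUT1), and of 23 chemokine and cytokine genes 1 rose (CXCL3), each also when adjusted over the list alone. The 25 lysosomal glycan degradation genes had 0 members called by limma over all probe sets and 0 adjusted over the list alone, but camera called the list higher, with a median change of 0.11 and an adjusted p of 0.00275. That call was lost with adjusted p = 0.739 with an estimated correlation, and fry gave 0.221. In the panel OGA, which removes O-GlcNAc from proteins, had 0.30 with a limma adjusted p of 0.222; OGT had 0.17, PODXL 0.14, GFPT1, CMAS and IGF1R 0.09 each, GNE 0.04 and GFPT2 -0.02, and 0 of the 8 were called.

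limma called 13 probe sets at 25 mM glucose, 7 higher and 6 lower, with 159 at an unadjusted p under 0.05; 4 of the called have no symbol and 0 changed at least 1.5-fold. With quantile normalization 2 were higher and 5 lower. Without normal culture replicate 1 limma called 0, with 96 at an unadjusted p under 0.05 and a smallest adjusted p of 0.0726, so none of the 9 named genes kept its call in every such fit. Without normal culture replicate 3 the count was 7, and a fit of only these 6 arrays called 0, with 135 at an unadjusted p under 0.05. POFUT1 was not called with its probe sets averaged.

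Glucose at 5 mM was compared with glucose-free medium, as parallel 24-hour treatments of the same label set. IL1B changed by -1.04 (SE 0.19), from 8.71 ± 0.14 without glucose to 7.67 ± 0.26 at 5 mM (SD, n = 3 each). SIGLEC15, a sialic acid-binding lectin, changed by -0.99 (SE 0.10, limma adjusted p = 9.69e-07), from 7.28 ± 0.05 to 6.29 ± 0.08. ST8SIA1 changed by -0.85 (SE 0.11), CHST9 by -0.70 (SE 0.12) and GNPDA1, the glucosamine-6-phosphate deaminase, by -0.60 (SE 0.10). CCL2, a chemokine for monocytes, rose 1.56-fold, from 10.88 ± 0.08 to 11.53 ± 0.06, and LFNG rose by 0.53 (SE 0.08). GFRA1, a co-receptor for GDNF, rose by 0.47, VEGFC by 0.42, INHBA by 0.41 and IGFBP3 by 0.38.

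Among the 25 measured genes of the lysosomal glycan degradation list 3 fell at 5 mM glucose, or 5 adjusted over the list alone, among them MANBA (beta-mannosidase, -0.44) and ASAH1 (acid ceramidase, -0.28). Camera called the list lower with an adjusted p of 0.00104, and the median change was -0.08; the call was lost with adjusted p = 0.515 with an estimated correlation, and fry gave 0.204. The lysosomal sialidase NEU1 changed by -0.49 (SE 0.08); it was the 1 of 7 genes called on the list of O-GlcNAc cycling and sialidases, also when adjusted over the list alone. Of 29 mucin-type O-glycan genes 2 fell, GALNT15 (-0.41) and GCNT3 (-0.38), and the same number adjusted over the list alone. Of 29 genes of the FGF, VEGF, PDGF and EGF family 2 rose, FGFR3 (0.47) and VEGFC, also adjusted over the list alone. Among 23 chemokine and cytokine genes 1 rose (CCL2) and 2 fell (IL1B and IL1A, the latter by -0.57), with 3 higher and 2 lower adjusted over the list alone. Of 8 insulin and IGF signalling genes 1 rose (IGFBP3). Fry called 2 lists in 1 direction, insulin and IGF signalling higher with an adjusted p of 0.00465 and O-GlcNAc cycling and sialidases lower with 0.0429, and it called 13 lists in its mixed form. Camera called neither of these 2 lists, with adjusted p values of 0.446 and 0.282, or 0.515 each with an estimated correlation. Of 20 sialyltransferase genes 1 fell (ST8SIA1), with 1 higher and 3 lower adjusted over the list alone. In the panel PODXL had -0.26, OGT and IGF1R -0.23 each, OGA 0.14, CMAS 0.08, GNE 0.06, GFPT2 0.05 and GFPT1 0.03, and limma called 0 of these 8.

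limma called 45 probe sets between 5 mM glucose and glucose-free medium, 12 higher and 33 lower, with 180 at an unadjusted p under 0.05; 8 changed at least 1.5-fold. Of the 32 named genes 17 stayed called without any 1 array, and 15 did in all fits, the other alternatives included; among the 17 were IL1B, SIGLEC15, ST8SIA1, CHST9, GNPDA1, NEU1, CCL2, LFNG, GFRA1, VEGFC, IGFBP3 and ASAH1, the last not called with its probe sets averaged (adjusted p = 0.0526). The calls of MANBA and IL1A were lost without glucose-free replicate 1 or 2 and without 5 mM replicate 1 or 3. The highest adjusted p values in those fits were 0.194 for MANBA and 0.239 for IL1A. INHBA, FGFR3, GALNT15 and GCNT3 also lost their calls in some of these fits, with adjusted p values up to 0.157, 0.206, 0.0830 and 0.182. A fit of only these 6 arrays called 109 probe sets and array weights gave 288; without glucose-free replicate 1 the count was 31, within 1.5 times the full count.

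**Figure D1:**
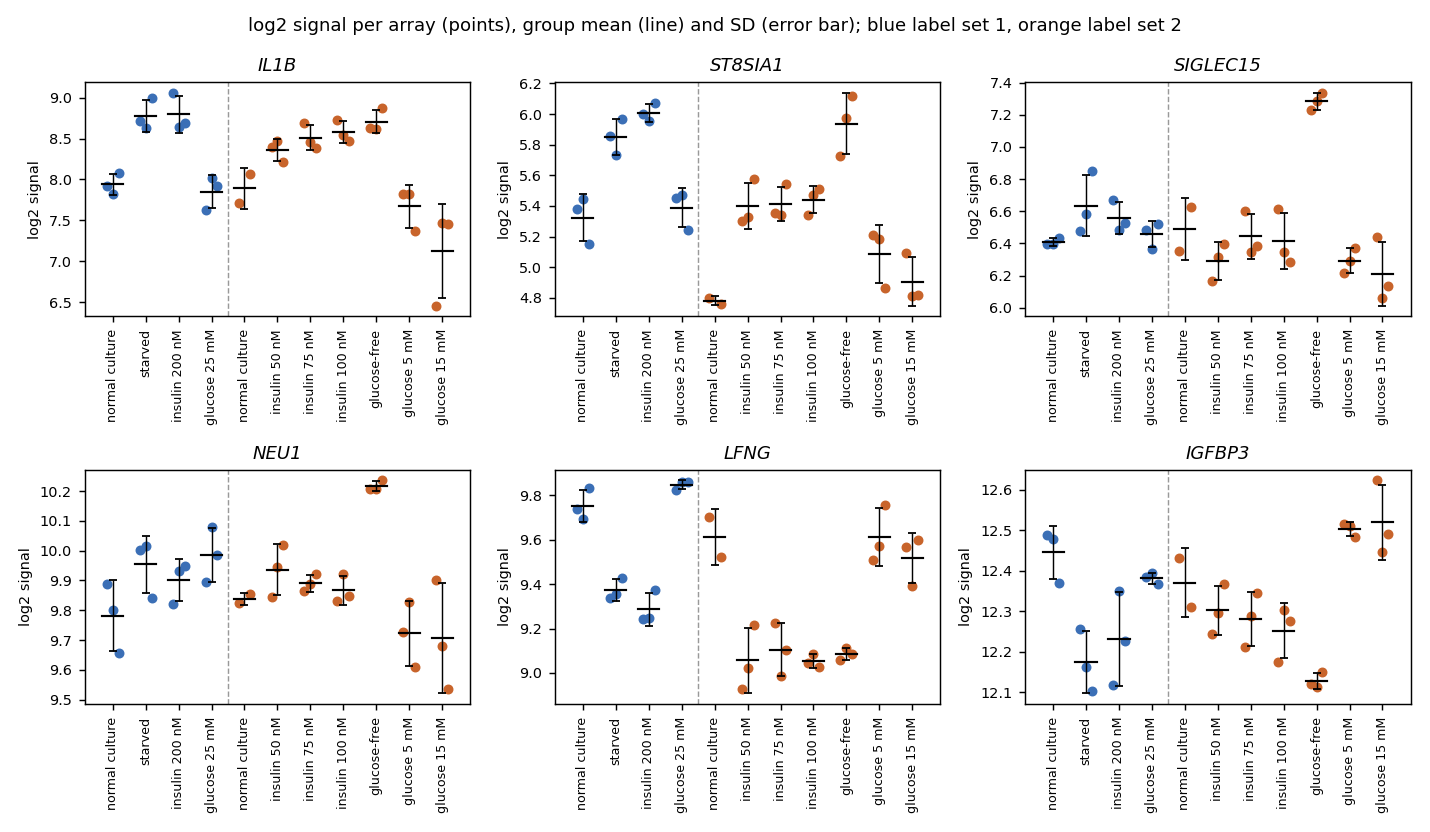
Log2 signal of IL1B, ST8SIA1, SIGLEC15, NEU1, LFNG and IGFBP3 on each array (vertical axis), by group (horizontal axis); points are arrays, coloured by label set, lines are group means and error bars the SD. IL1B lay at 8.71 in glucose-free medium, 7.67 at 5 mM and 7.13 at 15 mM glucose, and at 8.78 in starved cells against 7.94 in normal culture replicates 1 to 3.

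Glucose at 15 mM was compared with glucose-free medium in the same way. IL1B changed by -1.58 (SE 0.19, limma adjusted p = 4.26e-06), from 8.71 ± 0.14 to 7.13 ± 0.58 (SD, n = 3 each), and IL1A, the related interleukin-1 alpha gene, by -0.86 (SE 0.16). SIGLEC15 changed by -1.07 (SE 0.10), ST8SIA1 by -1.03 (SE 0.11) and CHST9 by -0.79. The colony-stimulating factor gene CSF2 changed by -1.18 (SE 0.30) and CXCL12 by -0.90 (SE 0.22), with a wide spread at 15 mM (7.84 ± 0.88 for CSF2). CCL2 rose by 0.63 (SE 0.12), INHBA by 0.53, CXCL3 by 0.52, TGFB2 by 0.49 and TNFRSF9 by 0.49. UAP1, the pyrophosphorylase that makes UDP-GlcNAc, rose by 0.43 (SE 0.12), and OGT, which transfers GlcNAc from it to proteins, changed by -0.48 (SE 0.14, adjusted p = 0.0220).

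The lysosomal glycan degradation list had 6 of 25 genes lower at 15 mM glucose and 0 higher, the same counts adjusted over the list alone. Among them were MANBA (-0.59), IDS (iduronate sulfatase, -0.39) and GUSB (beta-glucuronidase, -0.35). Camera called the list lower with an adjusted p of 0.00194 and a median change of -0.14; the call was lost with adjusted p = 0.999 with an estimated correlation, and fry gave 0.0708. On the list of O-GlcNAc cycling and sialidases 3 of 7 genes fell, OGT, NEU1 (-0.51) and its protective protein CTSA (-0.39), and 1 rose, NEU4 (0.24); adjusted over the list alone 2 were higher and 3 lower. Camera gave an adjusted p of at least 0.698 for each of the other lists, and fry called 0 lists in 1 direction and 18 in its mixed form.

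Of all 927 named genes on the array 125 were called at 15 mM glucose, the share to set beside each list count. Some enzymes that build N-glycans and O-glycans were among them. Of 23 Golgi N-glycan genes 5 fell and 1 rose (5 lower and 3 higher adjusted over the list alone), including ST6GAL1 (-0.38), FUT8 (-0.37) and MAN1A1 (-0.43). Of 20 sialyltransferase genes 3 fell, among them ST8SIA1 and ST3GAL6 (-0.44), and 1 rose, ST8SIA2 (0.28), the same counts adjusted over the list alone. Of 29 mucin-type O-glycan genes 3 fell, GALNT15 (-0.70), GALNT6 (-0.37) and GCNT3 (-0.36), and 2 rose, with GALNT16 at 0.30, also adjusted over the list alone. Of 13 fucosyltransferase genes 2 fell, FUT8 and FUT9 (-0.49), also adjusted over the list alone. Of 29 nucleotide sugar synthesis genes 2 rose and 3 fell, the latter GNPDA1 (-0.59), GALT (-0.27) and GALK2 (-0.23), also adjusted over the list alone. Of 20 nucleotide sugar transporters 1 fell, SLC35E3 (-0.22), but 0 by limma adjusted over the list alone. Of 20 N-glycan precursor and oligosaccharyltransferase genes 0 were called by limma either way, and of 3 genes of glycoprotein folding in the endoplasmic reticulum 0 were called over all probe sets and 1 was lower adjusted over the list alone. Of 7 O-mannose genes 1 rose, LARGE2 (0.22), of 7 GPI anchor genes 1 fell, PIGC (-0.24), and of 18 glycosphingolipid genes 1 fell, ST8SIA1; all 3 counts were the same adjusted over the list alone.

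Among proteoglycan genes, 5 of 32 on the heparan sulfate list fell, including HS2ST1 (-0.55), HS3ST1 (-0.39), HPSE (-0.35) and GLCE (-0.32), and 1 rose, also adjusted over the list alone. Of 28 proteoglycan core proteins 5 fell, among them TGFBR3 (-0.57), SPOCK3 (-0.53), VCAN (versican, -0.39) and GPC6 (-0.28), and 1 rose, with 3 higher and 5 lower adjusted over the list alone. Of 18 chondroitin and dermatan sulfate genes 1 fell, CHST9, also adjusted over the list alone. Of 8 hyaluronan genes 1 fell, HAS3 (-0.31), with its other probe set of opposite sign and 0 called by limma adjusted over the list alone. Of 13 galectin genes 1 fell, LGALS8 (-0.43), and 1 rose, CLC (0.21), with 3 higher and 2 lower adjusted over the list alone. Of 30 siglec and C-type lectin genes 3 fell, SIGLEC15, LY75 (-0.30) and CD69 (-0.28), and 2 rose, with MAG at 0.21, also adjusted over the list alone. Of 15 mucin genes 1 rose, MUC2 (0.30), also adjusted over the list alone.

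Of 23 genes of TGF-beta and BMP signalling 2 rose at 15 mM glucose, INHBA and TGFB2, and 6 fell, among them BMP4 (-0.49), with 2 higher and 8 lower adjusted over the list alone. Of 23 chemokine and cytokine genes 2 rose, CCL2 and CXCL3, and 4 fell, with 5 higher and 4 lower adjusted over the list alone. Of 29 genes of the FGF, VEGF, PDGF and EGF family 2 rose, FGFR3 (0.39) and HGF (0.17, with 1 of its 4 probe sets of opposite sign), and 2 fell, VEGFB (-0.69) and FGFR1 (-0.34), also adjusted over the list alone. Of 19 Notch pathway genes 1 rose, LFNG (0.43), and 1 fell, NOTCH2 (-0.48), and of 8 insulin and IGF signalling genes 1 rose, IGFBP3 (0.39); both counts were the same adjusted over the list alone. Of 6 adhesion molecule and integrin genes 1 rose, MCAM (0.27), and 1 fell, NCAM1 (-0.46, with its other probe set of opposite sign), also adjusted over the list alone. Of 4 genes of glucose uptake and glycolysis 1 rose, HK3 (0.19), also adjusted over the list alone.

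Of 3 podocyte markers 1 fell at 15 mM glucose, PLA2R1 (-0.33), the phospholipase A2 receptor, also adjusted over the list alone. Of 4 fibroblast and mesangial markers 1 fell, DCN (-0.25), also adjusted over the list alone. limma called 0 of 7 endothelial, 0 of 2 tubular and 0 of 4 leukocyte markers and 0 of 1 immediate early gene, over all probe sets and adjusted over the list alone; over all 1259 probe sets 335 had an unadjusted p under 0.05. In the panel only OGT was called; OGA had 0.26, IGF1R -0.29, PODXL -0.23, GNE -0.11, CMAS 0.11, GFPT2 0.07 and GFPT1 0.04.

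limma called 156 probe sets between 15 mM glucose and glucose-free medium, 60 higher and 96 lower, with 335 at an unadjusted p under 0.05; 19 changed at least 1.5-fold. The count was 57 without 15 mM replicate 2, and 82, 76 and 106 without glucose-free replicates 1, 2 and 3, the last within 1.5 times. Of the 70 named genes 30 stayed called without any 1 array, and 27 did in all fits; among the 30 were IL1B, IL1A, SIGLEC15, ST8SIA1, CHST9, GALNT15, VEGFB, MANBA, NEU1, GNPDA1, FUT8, HS2ST1, FGFR1, LGALS8, CCL2, INHBA, CXCL3, TGFB2, LFNG and IGFBP3. OGT lost its call without glucose-free replicate 2 or 3 and without 15 mM replicate 2 or 3, with adjusted p values up to 0.163, and also with quantile normalization. UAP1 lost it without glucose-free replicate 2 or 3 and without 15 mM replicate 1 or 2, with adjusted p values up to 0.0807. CSF2 and CXCL12 lost theirs without glucose-free replicate 1 or 15 mM replicate 3, with adjusted p values up to 0.0832 and 0.0693. CTSA, HAS3, CLC, HGF and NCAM1 lost theirs in each of the 6 fits without 1 array. The other genes among the 40 that did not stay called, with IDS, GUSB, ST6GAL1, MAN1A1, ST3GAL6, HS3ST1, VCAN, TGFBR3, MUC2, NOTCH2, PLA2R1 and NEU4 among them, lost theirs in at least 1 of the 6 fits. With array weights the count was 368.

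Glucose at 15 mM was also compared with 5 mM, which tests the difference between these doses directly. IL12A, a subunit of interleukin-12, had -0.36 (SE 0.08) and the neurotrophin gene BDNF -0.26 (SE 0.06). BMP4 had -0.43, HS3ST1 -0.31 and GDF15 -0.18, and these 5 smallest p values reached limma adjusted values of 0.177 to 0.401. In the panel OGT had -0.26, GNE -0.17, OGA 0.13, IGF1R -0.06, CMAS 0.03, PODXL 0.03, GFPT2 0.02 and GFPT1 0.01. limma called 0 probe sets, with 51 at an unadjusted p under 0.05, and 4, all lower, without 15 mM replicate 1.

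The comparisons of 5 mM and of 15 mM glucose with glucose-free medium share the 3 glucose-free arrays. In both, CCL2, LFNG, INHBA, IGFBP3 and GFRA1 rose and IL1B, SIGLEC15, ST8SIA1, NEU1 and GNPDA1 fell, among 10 probe sets higher in both and 32 lower in both. Independent lists of these sizes would share 0.572 and 2.52. The changes correlated with r = 0.849 over probe sets, which are not independent replicates, and simulated data without any change gave r = 0.500 from the shared arrays alone. In 100 such simulations a mean of 0.01 probe sets was called in both, against the 42 observed. The simulated noise was independent between probe sets. A deviation common to the 3 glucose-free arrays could also raise both values, and the simulation cannot tell this apart.

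Normal culture was present in both label sets, which allows a direct comparison of the sets under 1 condition. LUM, the matrix proteoglycan lumican, changed by -2.26 (SE 0.44), from 10.22 ± 0.22 in replicates 1 to 3 to 7.96 ± 2.32 in replicates 4 and 5 (SD, n = 3 and 2). That SE comes from the spread shared by all cells and understates the spread of replicates 4 and 5. The leptin receptor gene LEPR changed by -1.46 with 2 of its 3 probe sets of opposite sign, the transporter gene SLC35F5 by -1.46 and the transcription factor gene YY1 by -1.40. FLNA, which encodes filamin A, rose by 1.29 (SE 0.31), PODXL2 by 1.29 (SE 0.15), the linker enzyme gene B3GAT3 by 1.22 and the hyaluronidase gene HYAL2 by 1.19. In the panel OGA changed by -0.95, OGT by -0.80, GFPT1 by -0.78, CMAS by -0.60, IGF1R by -0.49 and GNE by -0.38, while PODXL had 0.18 and GFPT2 -0.15 and were not called. With replicate 5 left out, replicate 4 alone stood for set 2, and its spread was taken from the other cells. Calls and counts of fits without replicate 4 or 5, here and below, thus do not show that a change was replicated. Without replicate 5 LUM had -0.62, SLC35F5 -0.74, OGT -0.46, GFPT1 -0.49 and CMAS -0.25. In that fit YY1 had -0.36, FLNA 1.12, GNE -0.30 and IGF1R -0.36. IGF1R lost its call without replicate 2. Without replicate 4 LUM had -3.90, YY1 -2.44 and CMAS -0.94. limma called 567 probe sets, 315 higher and 252 lower in replicates 4 and 5. The count was 220 without normal culture replicate 5 and 763 without replicate 4, and a fit of only these 5 arrays called 106 and array weights left 34. Of 30 named genes 23 stayed called without any 1 array and 6 did in all fits.

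**Figure D2:**
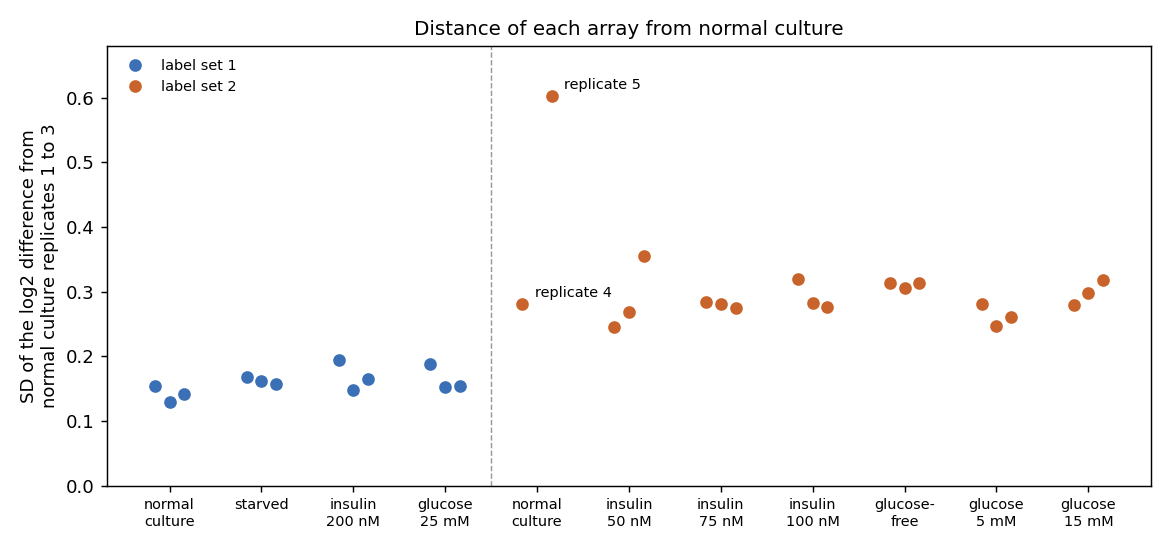
Distance of each array from the mean of normal culture replicates 1 to 3, as the SD of its log2 differences over probe sets (vertical axis), by group (horizontal axis), with points for arrays coloured by label set. Arrays of set 1 lay between 0.129 and 0.194, treated arrays of set 2 between 0.246 and 0.355, and normal culture replicates 4 and 5 at 0.281 and 0.603.

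Glucose-free medium was compared with normal culture replicates 4 and 5, the normal culture of its label set. SULT1C4, a sulfotransferase, rose 4.56-fold, from 7.65 ± 0.25 (n = 2) to 9.84 ± 0.02 (n = 3). LUM rose by 2.16 (SE 0.44), MAN1A1, a Golgi mannosidase, by 1.44 (SE 0.14) and ST8SIA1 by 1.16 (SE 0.12). CD74, the invariant chain of MHC class II, changed by -1.99 (SE 0.16), TGFB1 by -1.85 (SE 0.16), FLNA by -1.81 and the glypican gene GPC1 by -1.48. The pooled insulin groups differed from the same arrays by similar amounts, with -1.93 for CD74, -1.95 for TGFB1, -1.84 for FLNA and 2.01 for SULT1C4. These changes are therefore not particular to glucose-free medium. In the panel OGT rose by 1.12 (SE 0.15, limma adjusted p = 1.62e-06), GFPT1 by 0.67, IGF1R by 0.57, OGA by 0.48 and CMAS by 0.28, while GFPT2 had -0.29, GNE -0.17 and PODXL -0.17 and were not called. With normal culture replicate 5 left out LUM had 0.52 and GFPT1 0.38, both still called, while OGA (0.22, adjusted p = 0.203), IGF1R (0.45, adjusted p = 0.103) and CMAS (-0.061) lost their calls, CMAS also without glucose-free replicate 1. Without replicate 4 LUM had 3.80, OGA 0.74 and CMAS 0.63. With all 5 normal culture arrays pooled OGA had -0.091 and CMAS -0.074, neither called.

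limma called 802 probe sets between glucose-free medium and normal culture replicates 4 and 5, 201 higher and 601 lower; with quantile normalization 288 were higher and 343 lower. The median over all probe sets was -0.19, or -0.03 after quantile normalization. The count was 449 without normal culture replicate 5, 902 without replicate 4, 367 in a fit of only these 5 arrays and 119 with array weights. Of 28 named genes 24 stayed called without any 1 array, but 12 did in all fits, with SULT1C4, MAN1A1, ST8SIA1, CD74, TGFB1 and OGT among the 12. LUM lost its call with normal culture pooled (0.80, adjusted p = 0.185) and in the fit of only these arrays (0.110), GFPT1 with normal culture pooled (0.20, adjusted p = 0.307) and with array weights (0.142), and FLNA and GPC1 with array weights (0.0695 and 0.0542). No list was called by camera, which compares a list with the other genes, and fry called 19 of 26 lists in 1 direction.

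Glucose at 25 mM was compared with glucose-free medium through the normal culture of each label set, since these groups lie in different sets. The bridge takes the difference between the normal cultures as shared by all arrays of set 2, so a deviation of replicates 4 and 5 enters each bridged value. Over probe sets, the slope of the set difference of insulin-treated arrays on that of normal culture was 0.0764 (95% interval 0.0440 to 0.109), where a shared difference measured without noise gives 1. Noise in the normal culture arrays lowers that expected value. The interval treats probe sets as independent and leaves out the spread between arrays. The bridged change was 2.00 (SE 0.24) for ALG11, 1.97 for CD74, 1.95 for TGFB1 and 1.95 for FLNA, and it was -2.33 (SE 0.59) for LUM, -2.28 (SE 0.29) for SULT1C4 and -1.46 for MAN1A1. For CD74, TGFB1 and FLNA most of it came from glucose-free medium against replicates 4 and 5 (-1.99, -1.85 and -1.81). The pooled insulin groups shared that difference (-1.93, -1.95 and -1.84), so these bridged values cannot be credited to glucose. ALG11, LUM, SULT1C4 and MAN1A1 differed from replicates 4 and 5 by -1.42, 2.16, 2.19 and 1.44 in glucose-free medium. The pooled insulin groups had -1.47, 2.08, 2.01 and 1.21 there, so the bridged values of these genes cannot be credited to glucose either. The group means themselves were close for LUM, with 10.05 ± 0.07 at 25 mM and 10.11 ± 0.24 without glucose (SD, n = 3 each), and apart for SULT1C4, with 8.15 ± 0.29 and 9.84 ± 0.02. In the panel OGT had a bridged change of -0.96 with group means of 8.61 at 25 mM and 8.76 without glucose, and GFPT1 of -0.58 with 8.99 ± 0.04 and 8.79 ± 0.03, the opposite order; both were called. The other 6 had bridged changes that were not called: IGF1R -0.48, PODXL 0.32, GFPT2 0.26, GNE 0.21, CMAS -0.19 and OGA -0.18, the last with group means of 10.00 and 9.23. With normal culture pooled over the sets GFPT1 had 0.20 and OGT -0.15, neither called, and CMAS had 0.40 and OGA 0.77, both called. Without normal culture replicate 5 LUM had -0.69 and OGT -0.62, both still called, and GFPT1 had -0.29 and lost its call (adjusted p = 0.264). Without replicate 4 these genes had -3.97, -1.30 and -0.88. limma called 553 probe sets, 412 higher and 141 lower, and with quantile normalization 261 higher and 231 lower. The median over all probe sets was 0.17, or 0.02 after quantile normalization. Without normal culture replicate 5 the count was 320, in a fit of only the arrays compared 363, and with array weights 156. Of 26 named genes 19 stayed called without any 1 array and 9 did in all fits. No list was called by camera, and fry called 20 in 1 direction.

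Insulin at 50, 75 and 100 nM was compared with starved cells in the same bridged way, which asks for a dose response below 200 nM. TGFB1, the gene of a fibrosis-promoting cytokine, had bridged changes of -2.16, -2.06 and -2.10 (SE 0.22 each) at 50, 75 and 100 nM. Its group means were 6.64 ± 0.26, 6.74 ± 0.14 and 6.70 ± 0.02, against 7.98 ± 0.06 in starved cells (SD, n = 3 each). CD74 had -2.06, -1.98 and -2.07, with group means of 7.65, 7.72 and 7.64 against 9.04, and ALG11 had -1.85, -1.75 and -1.72, with means of 4.96, 5.06 and 5.09 against 6.87. SULT1C4 had bridged changes of 1.42, 1.96 and 2.02, with group means of 9.28, 9.82 and 9.88 against 8.45. The means of these genes cross the label sets. Glucose-free cells, not labelled as given insulin, differed from normal culture replicates 4 and 5 by -1.85 for TGFB1, -1.99 for CD74, -1.42 for ALG11 and 2.19 for SULT1C4. The pooled insulin groups had -1.95, -1.93, -1.47 and 2.01 there. These differences are therefore not particular to insulin. LUM had bridged changes of 2.04, 2.09 and 2.18 (SE 0.59), while its group means were 9.97, 10.02 and 10.11 against 10.19 ± 0.26 in starved cells. The chemokine gene CXCL5 had 1.31, 1.41 and 1.45 with group means of 10.73, 10.83 and 10.86 against 10.81, and the hyaluronan receptor gene CD44 had 1.30, 1.32 and 1.40 with means of 10.52, 10.54 and 10.62 against 10.50. Without normal culture replicate 5 these 3 genes lost their calls at every dose: LUM had 0.40, 0.45 and 0.54, CXCL5 had 0.20, 0.30 and 0.34, and CD44 had 0.14, 0.16 and 0.24, with adjusted p values from 0.0711 to 0.765. Without replicate 4 LUM had 3.68, 3.73 and 3.82, CXCL5 2.42, 2.52 and 2.56, and CD44 2.46, 2.47 and 2.55. At 50 nM the calls of CXCL5 and CD44 were also lost without normal culture replicate 1 or starved replicate 2, and that of CXCL5 without 50 nM replicate 3; at 75 nM that of CD44 was lost without normal culture replicate 1 or starved replicate 2.

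In the panel the bridged changes of OGA were 0.74, 0.67 and 0.71, those of GFPT1 0.74, 0.74 and 0.77, those of OGT 0.70, 0.67 and 0.66 and those of CMAS 0.40, 0.44 and 0.46 at 50, 75 and 100 nM insulin, all called. Their group means lay below those of starved cells at each dose: OGA had 9.46, 9.39 and 9.43 against 9.67, GFPT1 8.67, 8.67 and 8.70 against 8.72, OGT 8.47, 8.44 and 8.43 against 8.58, and CMAS 10.58, 10.61 and 10.63 against 10.77. All 4 genes changed sign with normal culture pooled over the label sets, where OGA had -0.21, -0.28 and -0.24 and none of these values was called. Bridged changes not called at any dose were -0.36, -0.33 and -0.28 for PODXL, -0.26, -0.10 and -0.16 for GFPT2, -0.19, -0.15 and -0.12 for GNE, and 0.13, 0.037 and -0.0014 for IGF1R. Leaving out normal culture replicate 5 gave GFPT1 0.44, 0.44 and 0.47, OGT 0.36, 0.33 and 0.32, and CMAS 0.060, 0.092 and 0.11, and all 3 lost their calls at each dose, with adjusted p values up to 0.0980, 0.279 and 0.742. OGA had 0.48, 0.41 and 0.45 and stayed called only at 50 nM, with adjusted p values of 0.0440, 0.0857 and 0.0527. Without replicate 4 OGT had 1.04, 1.01 and 1.00 and CMAS 0.75, 0.78 and 0.80; at 50 nM the call of CMAS was also lost without normal culture replicate 2, starved replicate 1 or 2, or 50 nM replicate 2. limma called 429 probe sets at 50 nM (124 higher, 305 lower), 491 at 75 nM (136 and 355) and 534 at 100 nM (139 and 395). With quantile normalization the splits were 211 and 212, 218 and 239, and 213 and 233. The medians over all probe sets were -0.12, -0.14 and -0.15, and -0.01 at each dose after quantile normalization. Without normal culture replicate 5 the counts were 196, 207 and 227, and without replicate 4 they were 683, 728 and 742 at 50, 75 and 100 nM. Fits of only the arrays compared called 123, 286 and 274, and array weights gave 43, 106 and 121. Of 28 named genes at each dose 16, 15 and 15 stayed called without any 1 array, and 5, 5 and 7 did in all fits. No list was called by camera, and fry called 15, 18 and 20 lists in 1 direction.

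The pooled insulin groups of 50, 75 and 100 nM were also compared with normal culture replicates 4 and 5. LUM rose by 2.08 (SE 0.38), SULT1C4 by 2.01 (SE 0.18), LEPR by 1.52 (with 1 of its 3 probe sets of opposite sign) and CXCL5 by 1.51, and TGFB1 changed by -1.95 (SE 0.14), CD74 by -1.93, FLNA by -1.84 and the agrin gene AGRN by -1.69. Glucose-free cells differed from the same arrays in the same direction, with -1.85 for TGFB1, -1.99 for CD74, -1.81 for FLNA and -1.35 for AGRN. They also had 2.16 for LUM, 2.19 for SULT1C4 and 1.48 for LEPR. The changes of the genes compared here are therefore not particular to insulin. In the panel OGT rose by 0.81, OGA by 0.68, GFPT1 by 0.57 and CMAS by 0.38, and PODXL changed by -0.32 and GNE by -0.25, while IGF1R had 0.17 and GFPT2 -0.02 and were not called. Glucose-free cells had 1.12 for OGT, 0.48 for OGA, 0.67 for GFPT1 and 0.28 for CMAS, so these rises are not particular to insulin either. When normal culture replicate 5 was left out LUM had 0.44, OGT 0.47 and OGA 0.42, all still called, while CXCL5 (0.40), GFPT1 (0.27), CMAS (0.037) and PODXL (-0.081) lost their calls, with adjusted p values of 0.144, 0.122, 0.753 and 0.753. Without replicate 4 GNE lost its call (-0.17, adjusted p = 0.146), and LUM had 3.72, CXCL5 2.61, GFPT1 0.87, CMAS 0.73 and PODXL -0.56. limma called 794 probe sets, 209 higher and 585 lower, and with quantile normalization 304 higher and 367 lower, with medians over all probe sets of -0.16 and -0.02. The count was 404 without normal culture replicate 5 and 140 with array weights. Of 30 named genes 22 stayed called without any 1 array and 15 did in all fits.

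Insulin at 100 nM and 50 nM lie in the same label set and were compared directly. CTNS, the lysosomal cystine transporter gene, had -0.60, the hyaluronan synthase gene HAS3 -0.49, KLRB1 -0.23, PSPN -0.21 and ERH 0.17, each with a limma adjusted p of 0.455. In the panel IGF1R had -0.13, GFPT2 0.10, PODXL 0.08, GNE 0.07, CMAS 0.05, OGT -0.04, OGA -0.03 and GFPT1 0.03. limma called 0 probe sets, with 82 at an unadjusted p under 0.05.

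**Figure D3:**
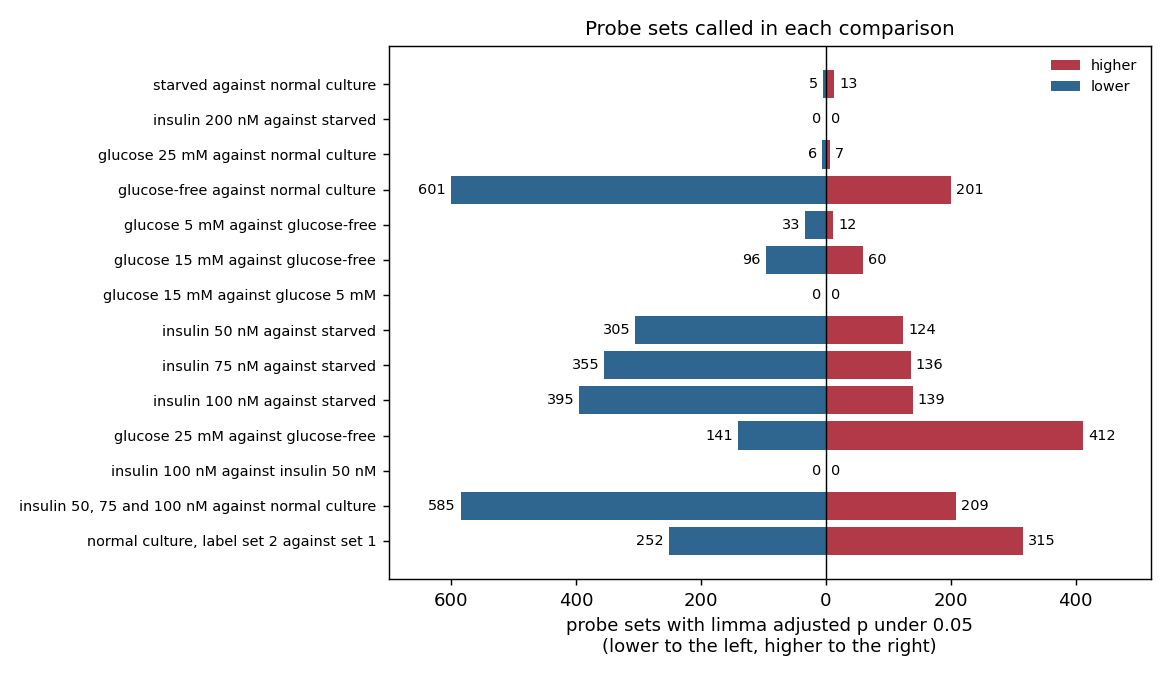
Number of probe sets called by limma at an adjusted p under 0.05 (horizontal axis), higher and lower, for each comparison. Comparisons within a label set and without normal culture replicates 4 and 5 called at most 156, and those that use these arrays called 429 to 802.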

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

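The tests of a difference between label sets and of a single deviating array were chosen only after the result was seen; the test of a wrong label and the counts over other groupings of the arrays were chosen before.

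Normal culture replicate 5 stood apart from the other 4 normal culture arrays in 8 of 69 measures, where its gap to the nearest array, divided by the range of the 5, was above Dixon's critical value of 0.71. Chance gives such a gap about 1 in 20 times, but most of the 69 are genes named for their change in comparisons that use replicates 4 and 5, and measures on 1 array are not independent, so the number of gaps is no test. The mean correlation with the other arrays was 0.972 on replicate 5 against 0.994 for the other normal culture arrays (ratio 0.840). Ratios for genes with a lower log2 signal on replicate 5 were 0.796 for LUM (6.32 against a mean of 10.06), 0.834 for CD44 (8.02 against 10.43), 0.832 for CXCL5 (8.19 against 10.62) and 0.826 for YY1 (7.54 against 9.89). They were 0.727 for the proteoglycan gene SRGN (8.32 against 10.25) and 0.745 for the ribosomal gene RPL23 (9.85 against 11.54). IFNG was higher on replicate 5, at 4.02 against 3.58, with a ratio of 0.833.

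Normal culture replicates 4 and 5 differed from replicates 1 to 3 by 567 called probe sets. A difference between the label sets, shared by all arrays of set 2, would have moved the insulin-treated arrays alike, but over probe sets the slope of their difference on that of normal culture was 0.0764 (95% interval 0.0440 to 0.109). That interval treats probe sets as independent and leaves out the spread between arrays. Noise in the normal culture arrays also lowers the slope that a shared difference would give. Replicate 5 as the single cause of the whole pattern is argued against by replicate 4, whose deviations correlated with those of replicate 5 over probe sets with a median r of 0.681, against at most 0.406 between replicate 5 and any treated array of set 2, though such arrays of different groups shared deviations among themselves (median r 0.673); probe sets are not independent replicates. A wrong label is argued against by distance, since replicate 4 lay 0.298 and replicate 5 lay 0.605 from the nearest treated group, while no other array lay more than 0.244 from its own group. That nearest group was 25 mM glucose, of label set 1, for both arrays. Their deviations correlated little with those of treated set 2 arrays, with a median r of 0.0716 for replicate 4 and 0.0515 for replicate 5. The wording alone therefore does not show that they match the treated arrays of set 2. RNA quality or a different state of these cultures may still account for the pattern, as neither was tested, and no biological explanation is given by the labels.

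For comparisons of 3 against 3 arrays there are 10 groupings, so the share with as many calls cannot be under 0.1. For starved against normal culture the real grouping called 18 and the highest other 1, so 1 of the 10 had as many. The real and highest other counts were 13 and 0 for 25 mM glucose against normal culture, 45 and 0 for 5 mM glucose against glucose-free medium, and 156 and 1 for 15 mM, where again 1 of 10 had as many. For 200 nM insulin against starved cells and for 100 against 50 nM insulin every grouping gave 0 by limma, with 42 and 82 probe sets at an unadjusted p under 0.05 in the real one. For 15 against 5 mM glucose the real count was 0 (51 at an unadjusted p under 0.05) and the highest other 1, so all 10 had as many.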

How the results depend on the processing

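All alternatives here were chosen before the data were examined, except leaving out normal culture replicates 4 and 5 together, which was chosen after seeing the data. Of 323 calls of a named gene in a comparison, 314 held with the trend and robust options, 290 with quantile normalization, 225 with array weights and 218 in fits of only the arrays compared, and 308 of 310 held with dim probe sets left out; the direction was kept in each of these. Over the fits without 1 array 2187 of 2580 such calls held, 392 were lost and 1 reversed. The limits lie in the 3 arrays per group, in normal culture replicates 4 and 5, and in signal over background, which was not measured. Except where stated, the cause was not tested.

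Without the label set, with normal culture pooled, 159 of 293 calls held, 99 were lost and 35 reversed. The 35 reversed values were not called in that fit, with limma adjusted p from 0.388 to 0.968. They show a lost call and no established change in the other direction. The counts were 33 for starved against normal culture, 61 for 25 mM glucose against normal culture, 91 for 15 mM glucose against glucose-free medium, 223, 189 and 252 for 50, 75 and 100 nM insulin against starved cells, and 346 for 25 mM glucose against glucose-free medium. Reversed log2 changes for glucose-free against normal culture were -0.091 for OGA and -0.074 for CMAS. At 50 nM insulin they were -0.22 for LUM, -0.066 for CXCL6, -0.079 for CXCL5, -0.17 for SLC35F5, -0.13 for HNRNPK, -0.21 for YY1, -0.21 for OGA, -0.046 for GFPT1, -0.11 for OGT and -0.19 for CMAS. At 75 nM they were -0.17 for LUM, -0.063 for IGFBP5, -0.12 for SLC35F5, -0.076 for YY1, -0.043 for HNRNPK, -0.25 for LEPR, -0.091 for DPM1, -0.28 for OGA, -0.048 for GFPT1, -0.14 for OGT and -0.16 for CMAS. At 100 nM they were -0.086 for LUM, -0.060 for SLC35F5, -0.047 for YY1, -0.065 for DPM1, -0.24 for OGA, -0.015 for GFPT1, -0.14 for OGT and -0.14 for CMAS. For 25 mM glucose against glucose-free medium they were 0.077 for HNRNPK, 0.24 for SLC35F5, 0.19 for YY1, 0.20 for GFPT1, 0.40 for CMAS and 0.77 for OGA; the last pair was not called with the label set and was called without it (adjusted p 0.0356 and 0.00524), which makes 37 reversed values in all. CMAS also reversed without normal culture replicate 5, to -0.061 for glucose-free against normal culture, against 0.63 without replicate 4.

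Label set as a random block (consensus correlation 0.589) gave 23 for 25 mM glucose against normal culture. A replicate block gave 39 for starved against normal culture, 32 for 25 mM glucose and 68 for 5 mM glucose against glucose-free medium. The numbers do not pair the arrays there, so these values are given only here. The blocked fit also left out normal culture replicates 4 and 5, so its counts do not show the effect of the block alone. Counts without these arrays and without a block are given below. Fits of only the arrays compared gave 4 for starved, 0 for 25 mM glucose (135 at an unadjusted p under 0.05 in limma), 367 for glucose-free against normal culture, 109 for 5 mM glucose, 123, 286 and 274 for 50, 75 and 100 nM insulin, 363 for 25 mM glucose against glucose-free medium and 106 between the normal cultures, with fewer arrays to estimate the spread. Quantile normalization gave 7 for 25 mM glucose against normal culture, and averaging by gene took starved from 14 genes to 8. Array weights, whose fit stopped before full convergence, gave 32 for starved, 119 for glucose-free against normal culture, 288, 368 and 11 for 5 mM and 15 mM glucose against glucose-free medium and 15 against 5 mM, 43, 106 and 121 for 50, 75 and 100 nM insulin, 156 for 25 mM glucose against glucose-free medium, 140 for the pooled insulin groups and 34 between the normal cultures. They gave normal culture replicates 4 and 5 the lowest weight, 0.0924 each.

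A minimum change of 1.5-fold left 5 for starved, 0 for 25 mM glucose (159 at an unadjusted p under 0.05 in limma before the minimum), 263 for glucose-free against normal culture, 8 and 19 for 5 and 15 mM glucose, 213, 230 and 250 for 50, 75 and 100 nM insulin, 269 for 25 mM glucose against glucose-free medium, 238 for the pooled insulin groups and 192 between the normal cultures, a stricter criterion by construction. Leaving out normal culture replicates 4 and 5 gave 31 for starved and 31 for 25 mM glucose, and 67 and 215 for 5 and 15 mM glucose against glucose-free medium. The lysosomal list lost its camera call in all 3 comparisons with an estimated correlation (adjusted p 0.739 at 25 mM, 0.515 at 5 mM and 0.999 at 15 mM) and was not called by fry (0.221, 0.204 and 0.0708). Without 1 array the lowest and highest counts were 2 and 11 for starved, 0 and 15 for 25 mM glucose, 449 and 902 for glucose-free against normal culture, 31 and 41 for 5 mM glucose, 57 and 120 for 15 mM, 0 and 4 for 15 against 5 mM, 196 and 683, 207 and 728, and 227 and 742 for 50, 75 and 100 nM insulin, 320 and 779 for 25 mM glucose against glucose-free medium, 404 and 877 for the pooled insulin groups and 220 and 763 between the normal cultures. The low value came without replicate 5 and the high one without replicate 4 in each comparison that uses these arrays of normal culture. Such fits leave 1 array of normal culture in set 2, so their counts rest on a spread taken from the other cells.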

Other observations

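The tests of chance alignment, of signal intensity and of the normal culture axis for starvation and glucose-free medium were chosen only after the result was seen; the other test here was chosen before its result was seen, as was taking the intensity trend and that axis out of the changes, which left r at 0.606 and 0.612 and decides nothing, since both hold little of the changes.

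Starved cells and glucose-free cells shared changes in opposite label sets, on arrays with no group in common. IL1B, ST8SIA1, CHST9, SPOCK3, SLC35F3 and RPL13A were higher in starved cells than in normal culture and lower at 5 mM glucose than in glucose-free medium, and these 6 genes were picked by that overlap, after their values were seen. In all 8 probe sets fell in this overlap, where independent lists of these sizes would share 0.341. LFNG, INHBA and IGFBP3 were lower in starved cells and higher at 5 mM glucose, 3 probe sets against 0.0477 for independent lists. In the other directions limma's lists shared 0 probe sets, with 151 at an unadjusted p under 0.05 for starvation and 180 for 5 mM glucose. Against 15 mM glucose the shared counts were 8 and 3, with 0.991 and 0.238 for independent lists.

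Over all probe sets, which are not independent replicates, the starvation change and the glucose-free minus 5 mM change correlated with r = 0.606 (rank correlation 0.540), and with r = 0.603 against 15 mM. Of 100 combined groupings of the arrays of both comparisons 1, the real one, had a correlation as large, for an exact permutation p of 0.01, the smallest they can give, and the highest other was 0.520. A smooth dependence of both changes on signal intensity is argued against as the whole cause, since such trends held 1.43% and 0.321% of the variance of the changes and carried 0.00570 of r, at most 0.0102 in size without any 1 array, where r was at least 0.520. The axis on which normal culture replicates 4 and 5 differ is argued against in the same way, since it carried -0.00181 of r, at most 0.0219 in size without any 1 array. A response common to withdrawal of serum and insulin and to withdrawal of glucose may account for the shared change; it was found and tested on the same data, and RNA quality and culture density stay open, as neither was tested.

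A response to higher glucose common to 25 mM against normal culture and 15 mM against glucose-free medium was a further hypothesis. The titles give no glucose level for normal culture, so the size of the step to 25 mM is unknown. The changes correlated over probe sets with r = -0.344 (rank correlation -0.404), the opposite of what the hypothesis predicts. Of 100 combined groupings 14 had a correlation as large in size (exact permutation p = 0.14, highest other 0.495). CXCL3, KLRC1 and TNFRSF9 were called higher in both comparisons, 3 probe sets against 0.334 for independent lists, and limma called 0 lower in both against 0.458 (159 and 335 at an unadjusted p under 0.05). As many were called in opposite directions, 1 probe set higher at 25 mM and lower at 15 mM (SULT1C2) against 0.534, and 2 the other way (MADCAM1 and 1 without a symbol) against 0.286.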
